A study of Gallus gallus with 4 samples.

How the data were processed

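The study profiled polyadenylated RNA from neural tube cells of chick embryos by RNA sequencing. Embryos were electroporated in ovo at Hamburger-Hamilton (HH) stage 11, a staging scale of chick development, either with the control plasmid pCIG at 2 µg/µl or with a mixture of 1 µg/µl Hoxb8-pCIG and 1 µg/µl pCIG. pCIG drives a gene of interest together with green fluorescent protein (GFP) from one transcript, so that GFP marks the cells that took up DNA. Fluorescent trunk neural tube was dissected after 18 hours, dissociated, and live GFP-positive cells were sorted. Per the labels' protocols, RNA was reverse transcribed and the cDNA was linearly amplified before library construction. The labels give 2 control and 2 Hoxb8 samples, numbered 1 and 2 in each group, with no day, batch or embryo pool. The p-values therefore measure only the spread between these samples, which may be technical.

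The file used here is the authors' deposited table of one comparison, Hox against WT, with 1 line per Ensembl gene and no values per library. WT was taken to be the pCIG control, since the labels hold no other group. Per the file's name the genes are those of Ensembl release 85 on the chicken build Galgal4. The submitters' processing notes name galGal4, Subread, featureCounts, DESeq and DESeq2, without roles, order or versions, and the aligner settings and the strand setting of the counting are not given in the sources used here.

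The authors' deposited columns were tested against each other before use. The authors' deposited signal is 1 mean per gene over the 4 libraries, of counts divided by a size factor per library, per the file headers and the repeated steps of the low values. The authors' log2 fold changes and their standard errors are on the log2 scale. The authors' Wald score equals the log2 fold change divided by its standard error (largest deviation 9.24e-14). The deposited p-values are the two-sided normal p-values of that score (largest deviation 2.78e-15), and the deposited adjusted p-values are Benjamini-Hochberg values over 12574 genes (largest deviation 1.89e-15). The table lists 17108 genes. Of these, 2247 had a mean of 0 and no p-value, and 2287 more had a p-value but no adjusted p because their mean lay below a cut between 17.47 and 17.49. The deposited standard errors peaked at 0.267 and had a median of only 0.114 among genes below that cut. An unmoderated standard error would grow there instead, so the fold changes are moderated toward 0 and understate changes of genes at low levels.

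Depth was read from the low means. Genes with a single read in a single library take one of 4 values, the worth of 1 read in each library, and all 1030 genes with a mean above 0 and under 3 are whole-number sums of these 4 steps within 1e-09, against 0 percent of 10000 random values in that range. The steps give size factors of 1.053, 1.051, 0.958 and 0.954. Every gene whose single read fell in either of the first 2 libraries has a positive deposited fold change and every such gene of the other 2 a negative one. The size factors on the Hoxb8 side of the table were thus 1.10 times those on the control side on average. Read totals per library were not derived. The mean total was 79237283 normalised counts per library, and the 10 most abundant genes held 4.39 percent of it. Counts per library were not derived for single genes, and no mean ± SD per group is given.

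Gene symbols come only from the table, which pairs 1432 of its 17108 Ensembl identifiers (8.37 percent) with a symbol. Its symbol column is headed as HGNC symbols, the human gene nomenclature, so a gene without one may still have a chicken gene name. The reference gene table at hand, of the later assembly GRCg7b, carries 0 Ensembl identifiers, so the other 15676 genes stay unnamed. It was used only to look up the gene order around HOXB8 and whether symbols are current (1348 of 1432 are). Antisense, overlapping and paralogous genes cannot be separated from these values.

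The main test, the rule for named genes and the 31 gene lists were fixed before the data were examined, as was what to do with a table of the authors' own comparison: their calls at an adjusted p under 0.05 are the main result and are described as theirs. The planned count model needs values per library and was not run. Genes are named by a fixed rule: HOXB8 and LZTS1; of genes with a symbol, an adjusted p under 0.05 and a mean of at least 50, the 15 with the lowest p and the 5 with the largest change in each direction; every measured HOX gene; and up to 4 members with the lowest p from each of 31 fixed gene lists. The part of the rule that asks for one direction in every pair of libraries could not be applied. A list with at least 5 tested members was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited scores, two-sided, with a preset correlation between genes of 0.01. An estimated correlation and the planned comparison of replicates need values per library and were not computed. Lists and alternatives chosen after seeing the data are named as such in the closing observations. Level-matched random lists (10000 draws within 10 level classes) and bootstrap intervals of medians (2000 resamples of genes, 95 percent) were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

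The alternatives were other filters on the mean, other thresholds on the adjusted p, other centrings of the fold changes, and scores divided by their central spread. On simulated fold changes with the real means and standard errors of the 12574 genes of this comparison, the centring recovered 91 percent of genes changed by 1 on the log2 scale and 39 percent of those changed by 0.5, with 10 false calls (7.14 percent of calls). The simulation treated genes as independent, with errors the size of the deposited standard errors and 200 changed genes. The real scores had a central spread of 1.69, and 15.2 percent of tested genes passed. These rates therefore need not hold for the real calls. On simulated scores that were independent between genes, the list test called 5 of 200 unchanged lists at an unadjusted p under 0.05 and found the 1 shifted list.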

Results

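RNA from GFP-sorted chick trunk neural tube cells was compared between embryos electroporated with Hoxb8-pCIG plus pCIG (2 libraries) and with pCIG alone (2 libraries), 18 hours after electroporation at HH stage 11. The comparison asks which transcripts change when the trunk homeobox gene Hoxb8 is added to neural tube cells, in a study on how HoxB genes act on neuronal delamination through Lzts1. The authors' deposited table held 17108 genes at a mean total of 79237283 normalised counts per library, of which 12574 had an adjusted p-value. Positive fold changes are higher in Hoxb8, as the title of the authors' deposited table gives the direction. Neither HOXB8 nor LZTS1 stands in that table under its symbol (0 lines each), so the electroporated gene and the gene of the study's title were not analysed here, and the direction could not be checked on the electroporated gene.

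Among the genes with a symbol, 30 of the 35 that changed at least 2-fold were higher in Hoxb8. TMEM27, which encodes the membrane protein collectrin, had the highest log2 fold change of them in the authors' deposited table, 3.38 ± 0.16 (standard error, here and below), a 10.4-fold rise at a mean normalised count of 1525 (adjusted p = 8.18e-101). FOXN4, a forkhead transcription factor of interneuron progenitors in the ventral spinal cord, rose by 2.11 ± 0.18 in the authors' deposited table (adjusted p = 4.20e-30), and EPB41L3, a membrane skeleton protein of the protein 4.1 family, by 1.92 ± 0.15 (adjusted p = 1.14e-36). In the authors' deposited table CALB2, which encodes the calcium-binding protein calretinin, rose by 1.75 ± 0.24, the secreted factor gene FAM19A2 by 1.84 ± 0.27 and the guidance cue gene SEMA5A, the 1 tested member of the axon guidance list, by 1.26 ± 0.17. The LIM-only cofactors LMO2 and LMO3 rose by 1.48 ± 0.17 and 1.08 ± 0.16 in the authors' deposited table, and the zinc finger gene TSHZ2 rose by 1.10 ± 0.17. PPP1R3B, a glycogen-targeting subunit of protein phosphatase 1, rose by 1.96 ± 0.21 and the co-chaperone gene BAG3 by 0.93 ± 0.14 in the authors' deposited table. The other 4 of the 15 risers with a symbol that had the lowest p were TPD52L1 (1.75), C11orf87 (1.66), SIDT1 (1.10) and ANKRD50 (0.84), each as a log2 fold change in the authors' deposited table.

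The falling genes included 2 transcription factors of the dorsal neural tube. In the authors' deposited table LMX1A, a LIM homeobox gene of the roof plate, fell by 1.05 ± 0.15 on the log2 scale (adjusted p = 2.71e-10) and PAX3, a paired box gene of dorsal progenitors, by 0.82 ± 0.12 (adjusted p = 4.87e-10). ACKR3, the scavenging receptor of the chemokine CXCL12, had the lowest p of the falling genes with a symbol, with a log2 fold change of -1.03 ± 0.12 in the authors' deposited table (adjusted p = 1.15e-15). PTN, the heparin-binding growth factor pleiotrophin, fell by 0.98 ± 0.12 at a high mean of 19080 normalised counts over the 4 libraries, and the kinase gene PIM1 fell by 0.90 ± 0.13, both in the authors' deposited table. The potassium channel gene KCNJ5 (-1.09 ± 0.16), the helix-loop-helix gene TAL2 (-1.06 ± 0.21) and RASSF9 (-1.04 ± 0.22) had the other log2 fold changes below -1 among called genes with a symbol in the authors' deposited table. The other 8 of the 15 falling genes with a symbol that had the lowest p were, in the authors' deposited table, ZBTB18 (-0.82), PRELP (-0.78), SULF1 (-0.77), NTN3 (-0.75), MURC (-0.69), APC2 (-0.67), PTPRN2 (-0.66) and HOXB9 (-0.63), each as a log2 fold change.

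**Figure D1:**
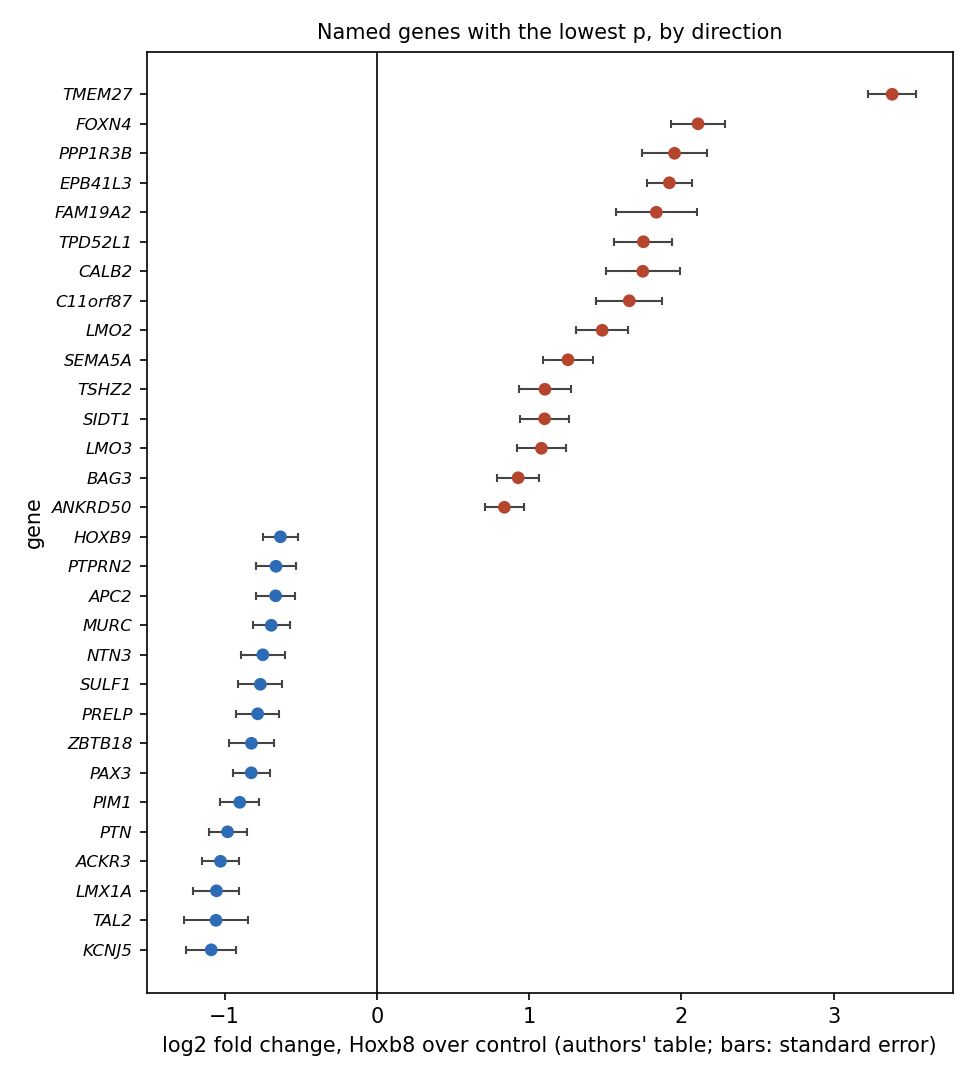
Log2 fold changes of Hoxb8 over control (x axis, with the authors' standard errors as bars) of the 15 named genes with the lowest p in each direction (y axis), red for higher and blue for lower in Hoxb8. The rises run from 0.84 for ANKRD50 to 3.38 for TMEM27, while the falls lie between -0.63 for HOXB9 and -1.09 for KCNJ5.

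Of the Hox genes with a symbol, 1 of 4 tested passed the threshold. HOXB9, a posterior HoxB gene, fell by 0.63 ± 0.12 on the log2 scale in the authors' deposited table (adjusted p = 1.99e-06, mean 11446). HOXB7, which neighbours HOXB8 in the reference gene order, stood at -0.16 ± 0.12 in the authors' deposited table (adjusted p = 0.429, mean 7280), HOXD10 at -0.48 ± 0.24 (adjusted p = 0.169, mean 356) and HOXD11 at -0.033 ± 0.21 (adjusted p = 0.943, mean 20.2). Adjusted over the list alone the count was also 1. HOXC6, HOXC11 and HOXC12 were listed at 0 in the authors' deposited table, as were the ribosomal protein genes RPL17, RPL34 and RPS26, so a 0 there does not show that a gene was silent. Centred on genes of like level, HOXD10 passed too (log2 fold change -0.66, adjusted p = 0.0438, against a range of 0.0438 to 0.906 over all settings tried).

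The lists of junction and delamination genes held 7 tested members, of which 1 changed. RND3 fell by 0.38 ± 0.13 on the log2 scale in the authors' deposited table (adjusted p = 0.0209), a call that ended when fold changes were centred on genes of like level (-0.29, adjusted p = 0.109, against a range of 0.0194 to 0.632 over all settings tried). LZTS2, a paralogue of LZTS1, stood at 0.36 ± 0.16 in the authors' deposited table (adjusted p = 0.112). Adjusted over the list alone, 1 delamination gene was higher (LZTS2) and 1 lower (RND3), and RHOU stood at -0.062 ± 0.15 in the authors' deposited table. Of 4 apical junction and polarity genes 0 passed in the authors' DESeq2 comparison (0 also adjusted over the list alone, 1 at an unadjusted p under 0.05): PARD3B stood at 0.25 ± 0.13 (adjusted p = 0.182), NECTIN1 at 0.13 ± 0.13, LLGL1 at 0.096 ± 0.14 and SCRIB at -0.13 ± 0.11 in the authors' deposited table. With the median of the genes over 10000 set to 0, LZTS2 and PARD3B passed (adjusted p = 0.0178 and 0.0216), while their highest adjusted p over all settings tried were 0.859 and 0.917.

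Single genes of the signalling and patterning lists changed, in both directions. Both tested genes of the dorsal list fell (LMX1A and PAX3), and PAX3 was also the 1 tested member of the neural crest list. Of 3 Notch pathway genes in the authors' deposited table, NRARP, a feedback inhibitor and target of Notch, fell by 0.56 ± 0.14 (adjusted p = 0.000975), the coactivator gene MAML2 rose by 0.49 ± 0.14 (adjusted p = 0.00375), and DTX1 stood at -0.26 ± 0.17 (adjusted p = 0.354). In the retinoid list RDH10, which makes retinaldehyde for retinoic acid synthesis, rose by 0.68 ± 0.15 and the nuclear receptor corepressor NRIP1 fell by 0.59 ± 0.14 in the authors' deposited table (adjusted p = 0.000263 and 0.000260). CDX2, a homeobox gene of the posterior axis and tail bud, rose by 1.17 ± 0.26 at a low mean of 191 in the authors' deposited table (adjusted p = 0.000116), and LIN28B stood at -0.091 ± 0.12. Of 3 WNT pathway genes 0 passed over all genes in the authors' DESeq2 comparison (2 at an unadjusted p under 0.05): RNF43 stood at 0.63 ± 0.25 (adjusted p = 0.0614), SP5 at 0.52 ± 0.27 and NKD1 at -0.24 ± 0.13 in the authors' deposited table. Adjusted over the list alone, RNF43 passed in the WNT list, ID3 (-0.32 ± 0.12) in the progenitor and BMP lists and SESN2 (-0.52 ± 0.20) in the list of p53 targets, with values from the authors' deposited table. Apart from these lists and the delamination list described above, the counts of the fixed lists adjusted over the list alone equalled those over all genes. MEIS1 (-0.067), EVX1 (0.0022), UNCX (-0.067), SPRED1 (-0.043), GRHL2 (-0.49), CENPA (0.26), INHBB (0.35) and DHX58 (0.41), members of the Hox cofactor, interneuron, mesoderm, FGF, surface ectoderm, mitosis, BMP and interferon lists, did not pass and are given as log2 fold changes in the authors' deposited table. EVX1, INHBB, DHX58 and GRHL2 had low means (34.6, 45.6, 42.1 and 95.4) and standard errors of 0.25, 0.26, 0.26 and 0.26. Their moderated values do not show an absence of change.

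**Figure D2:**
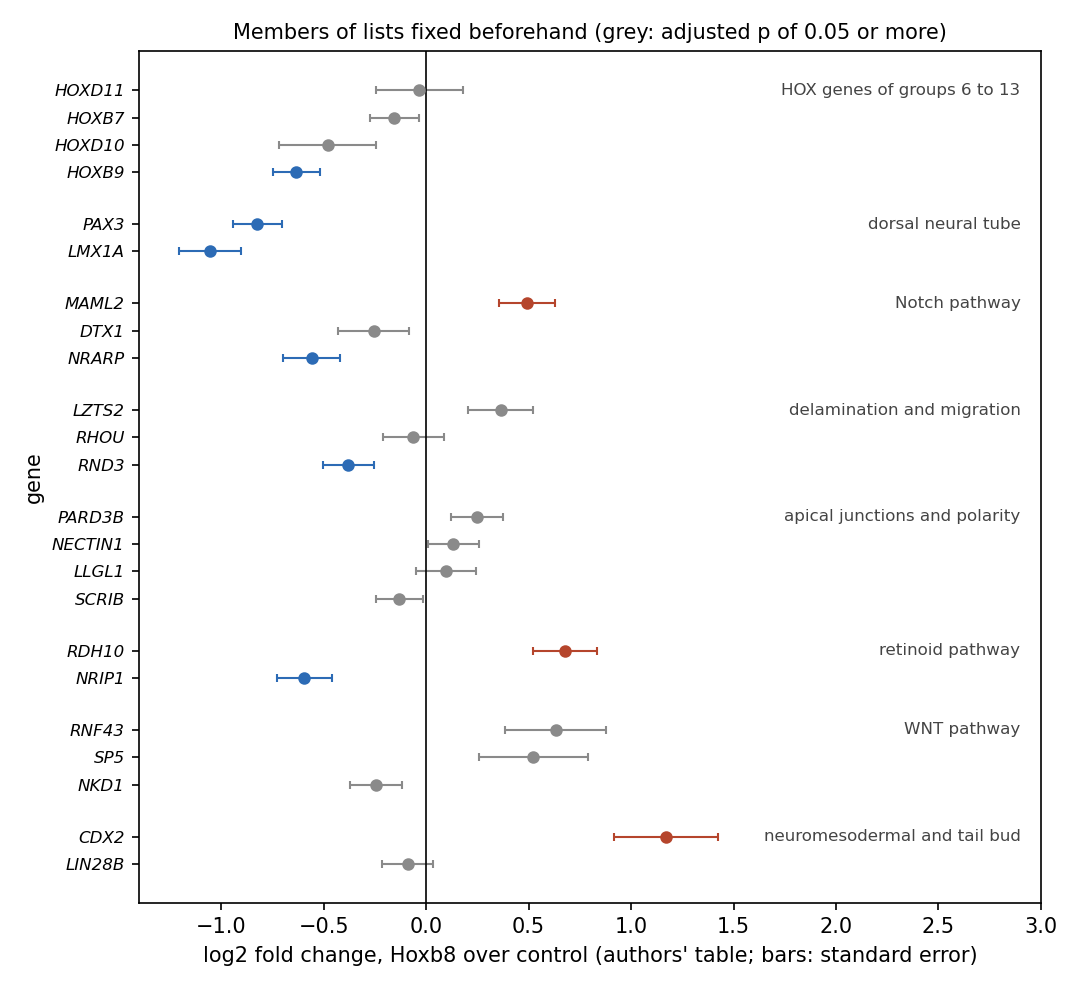
Log2 fold changes of Hoxb8 over control (x axis, with the authors' standard errors as bars) of the tested members of 8 lists (y axis, list names at the right), in red or blue where the adjusted p was under 0.05 and in grey otherwise. PAX3 and LMX1A lie at -0.82 and -1.05, and CDX2 at 1.17.

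Markers of other cell types and of RNA quality had few tested members. Of the blood and endothelium list LMO2 rose, as above, while the endothelial gene PECAM1 stood at -0.028 ± 0.27 in the authors' deposited table (adjusted p = 0.963, mean 1998). The standard error of PECAM1 was 1.78 times the median of genes at its level. In the stress list BAG3 rose, as above, and DNAJB9 (-0.23 ± 0.13) and ATF3 (-0.13 ± 0.19) did not pass in the authors' deposited table. Of 7 ribosomal protein genes 0 passed in the authors' DESeq2 comparison (0 also at an unadjusted p under 0.05). The ribosomal list was the 1 fixed list large enough for a list test. Set against all other tested genes, its Wald scores were not shifted past the threshold (cameraPR of limma, two-sided, adjusted p = 0.640). That test did not allow for the high mean level of these genes. With scores centred on genes of like level, a setting chosen after seeing the data, the list did not pass either (cameraPR of limma, adjusted p = 0.101). In a comparison outside the planned tests, its median log2 fold change of 0.086 lay above 99.1 percent of the medians of 10000 random lists matched on mean level. The central 95 percent of these medians ran from -0.31 to 0.048. Random lists do not carry the correlation between genes of one family, so this rank does not show a shift. Of the 31 fixed lists, 8 had no tested member with a symbol and so gave no result: Hox groups 1 to 5, neurogenic commitment, postmitotic neurons, motor neurons, ventral neural tube, S phase, G1 cyclins with CDK inhibitors, and mitochondrially encoded genes. In all, 12 of 46 distinct list genes passed, 6 higher and 6 lower.

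Over all genes, 1913 of 12574 passed an adjusted p under 0.05 in the authors' deposited table, 1097 higher and 816 lower in Hoxb8. Changes of at least 2-fold were mostly rises, 251 of 276. The gene with the lowest p in each direction carried no symbol. Of the genes without one, ENSGALG00000026853 and ENSGALG00000028376 rose 19.0-fold and 16.7-fold in the authors' deposited table, and ENSGALG00000014908 and ENSGALG00000028415 had log2 fold changes of -1.67 ± 0.14 and -1.59 ± 0.14. Of the genes with a symbol 206 of 1157 passed (127 higher, 79 lower), against 1707 of 11417 without one (Fisher's exact test across genes, two-sided, p = 0.0112). The higher share of calls was 61.7 percent with and 56.8 percent without a symbol (Fisher's exact test, two-sided, p = 0.205). Neither test allows for level, and the median mean was 1481 with and 2427 without a symbol. Both also treat genes of the same libraries as independent.

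The direction of the calls followed the mean level of the gene. At means of 100 to 1000 normalised counts, 461 of 539 called genes were higher in Hoxb8, whereas over 10000 only 46 of 359 were. The median log2 fold change of all genes fell from 0.15 (95% bootstrap interval 0.14 to 0.17) at 100 to 1000 to -0.12 (-0.13 to -0.12) over 10000. These intervals resample genes and do not measure the spread between libraries. Centred on genes of like level, 1587 genes passed, 955 higher and 632 lower, of which 1371 were among the 1913. With the median of the genes over 10000 set to 0, a shift of 0.12, 1849 genes were higher and 361 lower (83.7 percent higher, against 57.3 percent as deposited). Among the 37 named genes that passed, RND3 lost its call under these 2 centrings and the others kept their direction and call.

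**Figure D3:**
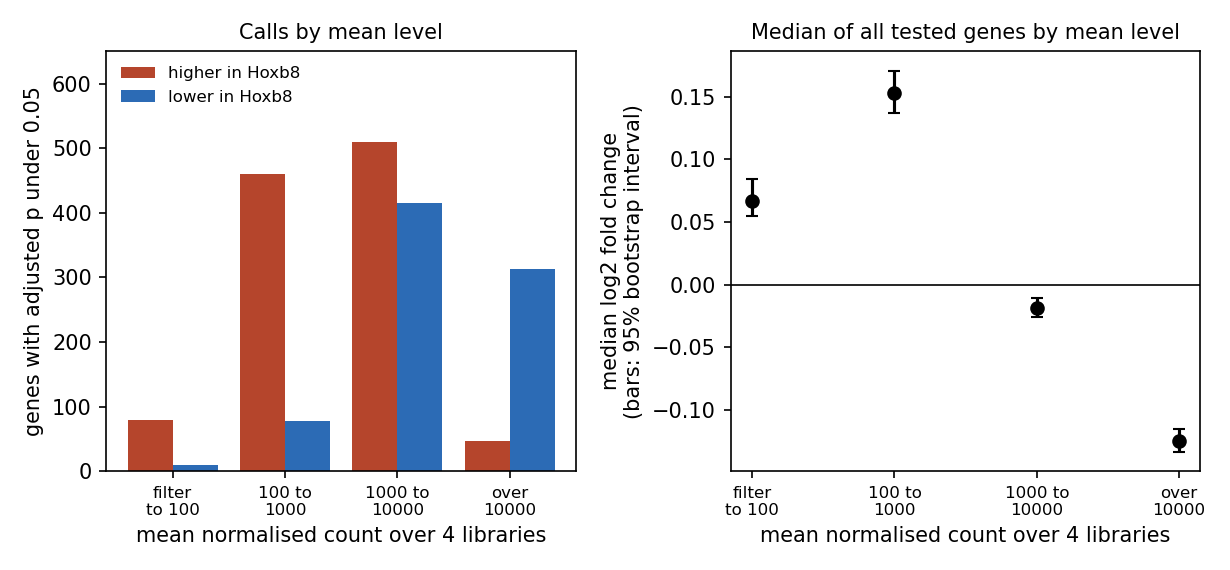
Left, genes with an adjusted p under 0.05 (y axis, number of genes) that were higher (red) or lower (blue) in Hoxb8, by mean normalised count over the 4 libraries (x axis). Right, the median log2 fold change of all tested genes (y axis, bars are 95% bootstrap intervals over genes) in the same level classes, which is 0.15 at 100 to 1000 and -0.12 over 10000.

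The deposited p-values rest on 2 libraries per group, and the central spread of the Wald scores over the tested genes was 1.69. Unchanged genes alone would give 1 only without moderation of the fold changes, and less with it. Below the authors' filter, 21 of 2287 genes had an unadjusted p under 0.05. With the scores divided by 1.69, a choice made after seeing the data, 312 genes passed (237 higher, 75 lower). The error rate of these calls is not known. Of the 37 named genes that passed as deposited, 25 were still among them, including TMEM27, FOXN4, EPB41L3, ACKR3, PAX3, LMX1A and HOXB9, and 12 were not: TAL2, RASSF9, SULF1, NTN3, PTPRN2, APC2, RND3, CDX2, NRARP, MAML2, RDH10 and NRIP1.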

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

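The alternatives that centre fold changes or divide scores by their spread were chosen after seeing the data, and the filters and thresholds before. No paired analysis was possible because the deposited table gives no values per library and nothing ties a size factor to a replicate number. Reads per library were not derived from the means, so leaving out single libraries and the other normalizations, count models, pseudocounts and list tests set beforehand were not run. The 1913 calls became 1796 with no filter on the mean, 1912 at a mean of at least 50 and 1608 at a mean of at least 396 (799 higher and 809 lower, 49.7 percent higher against 57.3 percent). At that last filter 31 of the 37 named genes that passed were tested and kept their call. There 9452 rather than 12574 genes were tested, and 154 rather than 276 changed at least 2-fold. The 1913 calls became 2491 at an adjusted p under 0.1, 1184 at under 0.01 (431 lower), 1883 centred on the median of all genes (whose median was -0.0053), and 1587 centred on genes of like level. With genes over 10000 set to a median of 0, 1849 were higher and 361 lower, by construction of the shift. With scores divided by their central spread 312 remained, 237 higher and 75 lower. Of the 37 named genes that passed, 12 lost their call under that last setting (SULF1, NTN3, PTPRN2, APC2, TAL2, RASSF9, NRARP, MAML2, RND3, CDX2, NRIP1 and RDH10), and RND3 also did under an adjusted p of 0.01 and both centrings with level. Reversed directions occurred only in named genes that never passed: centred on genes of like level, MEIS1 (0.0549), LIN28B (0.0417) and EVX1 (-0.0683); with genes over 10000 at 0, HOXD11 (0.0913), MEIS1 (0.0574), RHOU (0.0626), UNCX (0.0579), LIN28B (0.0337), PECAM1 (0.0968) and SPRED1 (0.0813), all log2 fold changes whose deposited size was smaller than the shift. The potassium channel list, which did not pass as deposited, changed direction in that test when centred (adjusted p = 0.683), although its centred median stayed above 0 (0.032), and the cause was not tested. Calls gained were HOXD10 and SESN2 (centred on genes of like level, SESN2 also at a mean of at least 396), PARD3B, LZTS2 and RNF43 (genes over 10000 at 0), and ID3, RNF43 and SESN2 (adjusted p under 0.1). Depth, at 79237283 normalised counts per library, limits the 2287 genes under the authors' filter, where 21 had an unadjusted p under 0.05.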

Other observations

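All tests in this part were chosen after the results were seen. The genes and the 4 lists described first were not among the lists fixed beforehand and were chosen after their values were seen. Some members, such as CENPA and PTPRN2, also stood in a fixed list or were named by the fixed rule. Of 45 tested genes of neuronal vesicles, synapses and neuropeptides, 13 rose and 3 fell (14 and 4 adjusted over the list alone). In the authors' deposited table the risers included NXPH2, a neurexin ligand, at a log2 fold change of 1.43 ± 0.24, the prohormone convertase gene PCSK1 at 1.13 ± 0.21, UNC13B, a synaptic vesicle priming factor, at 0.98 ± 0.20, and the secretogranin gene SCG2 at 0.74 ± 0.21. LGI1 (-0.55 ± 0.15), NPTXR (-0.40 ± 0.14) and PTPRN2 (-0.66 ± 0.13) fell in the authors' deposited table. Centred on genes of like level, SCG2 no longer passed (0.56, adjusted p = 0.0542), and with genes over 10000 at 0 NPTXR did not (-0.27, adjusted p = 0.171). Of 26 genes of DNA replication, repair and mitosis 0 rose and 6 fell in the authors' DESeq2 comparison (7 fell adjusted over the list alone, and 1 was higher and 8 lower at an unadjusted p under 0.05), among them SMC5 (-0.43 ± 0.12) and ERCC6L (-0.41 ± 0.14) in the authors' deposited table. Of 20 genes of ribosome biogenesis and RNA processing 0 rose and 5 fell in the same comparison (7 fell adjusted over the list alone, and 0 were higher and 9 lower at an unadjusted p under 0.05), among them TSR1 (-0.42 ± 0.12) and SRSF1 (-0.33 ± 0.12) in the authors' deposited table. Centred on genes of like level, ERCC6L (-0.32, adjusted p = 0.127), TSR1 (-0.30, adjusted p = 0.0724) and SRSF1 (-0.20, adjusted p = 0.301) kept their direction without passing, and with genes over 10000 at 0 these 3 and SMC5 (-0.31, adjusted p = 0.0538) did not pass either. Of 18 potassium channel genes 3 rose and 1 fell (5 and 1 adjusted over the list alone), and this list did not pass (cameraPR of limma, adjusted p = 0.470).

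Of the 127 genes with a symbol that rose in the authors' deposited table, only some outside any tested list are given here. They were picked without a fixed rule and include WNT16 (log2 fold change 0.94 ± 0.23), RSPO2 (0.84 ± 0.18), SFRP4 (0.64 ± 0.21) and SOSTDC1 (0.55 ± 0.19). LGR6, which encodes an R-spondin receptor, fell by 0.69 ± 0.23 in the authors' deposited table. CXCL12 rose by 0.52 ± 0.17 in the authors' deposited table while its receptor gene ACKR3 fell. FAM19A2, FAM19A3 and FAM19A4 rose by 1.84, 1.23 and 0.71 in the authors' deposited table and FAM19A1 stood at 0.017, which turned to -0.064 when centred on genes of like level. TSHZ3 rose by 0.38 ± 0.12 along with TSHZ2 in the authors' deposited table, and TSHZ1 stood at -0.28 ± 0.12 (adjusted p = 0.0931). Centred on genes of like level, CXCL12 (0.44, adjusted p = 0.0651), FAM19A4 (0.54, adjusted p = 0.0692), SFRP4 (0.49, adjusted p = 0.105) and SOSTDC1 (0.40, adjusted p = 0.172) no longer passed, and with genes over 10000 at 0 LGR6 did not (-0.56, adjusted p = 0.0694). With scores divided by their central spread, FAM19A2, TSHZ2, ACKR3 and NXPH2 still passed, and the other genes named in these 2 paragraphs as rising or falling did not. In that setting 3 of the 16 neuronal calls, 0 of the 6 replication calls, 0 of the 5 ribosome biogenesis calls and 1 of the 4 potassium channel calls remained. Among the genes with a symbol, the standard error exceeded the median of genes of like level the most for FAM181B (2.08 times), SP5 (2.07 times), TMUB1 (2.05 times) and PECAM1 (1.78 times). Their standard errors (0.266, 0.267, 0.263 and 0.265) lay near the largest of all genes, 0.267. Because the deposited values are moderated, these ratios may understate the spread of these genes.

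In 3 of these lists most members lay on one side: the median log2 fold change was 0.21 for the neuronal, -0.20 for the replication and -0.23 for the ribosome biogenesis genes. Because the members were put together after their values were seen, a list test cannot show that these groups move. Centring on the shift with level left medians of 0.17, -0.19 and -0.17, so that shift does not account for all of their size. Each centred median lay outside the central 95 percent of level-matched random lists (largest adjusted p of the 3 lists 0.0313, cameraPR of limma). Members picked after their values were seen can give this under any cause, so neither comparison decides on one. What remains after centring may come from that choice. Which genes carry a symbol stays open (largest adjusted p 0.00425 against those genes alone). A larger share of differentiating neurons among the sorted cells, which may be an effect of Hoxb8 or of dissection, also stays open, because the fixed neurogenic and postmitotic lists had 0 tested members with a symbol. Among neuronal genes of the list chosen afterwards, RBFOX3 rose by 0.47 in the authors' deposited table (adjusted p = 0.0440), a call lost with scores divided by their central spread. CELF3 (0.19), CELF5 (0.043), TRIM9 (-0.075) and MAP1A (-0.27), given as log2 fold changes in the authors' deposited table, did not pass. These genes were picked without a fixed rule and need not represent the list, in which 13 of 45 tested members rose and 3 fell.

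The lean of the calls toward higher at low and lower at high mean levels is not what a constant offset of the authors' scaling would give, since the median log2 fold changes at means of 100 to 1000 and over 10000 differed by 0.28. A smooth shift shared by all genes of a level, as unequal amplification or background reads might produce, would leave calls near balance after centring. After centring, 63.7 percent of 479 calls at 100 to 1000 were higher in Hoxb8 (exact binomial interval 59.2 to 68.0) and 44.4 percent of 207 over 10000 (37.6 to 51.5). These intervals treat genes of the same libraries as independent and do not measure the spread between libraries. Centring itself brings calls toward balance, so the values over 10000 support no explanation, and the interval at 100 to 1000 reaches below the bound of 60 percent set for the test, which leaves the shared shift open. For the other level classes the test set no bound. At means under 100, 75.8 percent of 66 centred calls were higher (63.6 to 85.5), and at 1000 to 10000, 60.8 percent of 835 (57.4 to 64.2). The size factors on the Hoxb8 side were also 1.10 times as large, a difference that the scaling removes on average. Induction of weakly expressed genes by Hoxb8 is the biological alternative, and with 2 libraries per group and no values per library it was not tested.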
